A study of Homo sapiens with 6 samples.

How the data were processed

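RNA from normal human myoblasts, the mononucleated precursors of muscle fibres, was measured on 6 whole-transcript oligonucleotide arrays. Of these, 3 held cells with long telomeres (15 kb) and 3 cells with short telomeres (6 kb), called biological replicates in the labels. Per the labels' protocols, the cells had received a removable telomerase (hTERT) cassette that lengthened the telomeres, the cassette was excised at different times, and the cells were then grown to similar population doublings, with telomere length read from terminal restriction fragments. Total RNA was labelled as sense-strand DNA. The labels do not say whether the replicates came from separate donors or separately excised cultures. The p-values of single genes therefore measure the spread between these samples, which may be partly technical.

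The deposited values are log2 intensities per array row, and the submitters' processing notes name RMA, oligo and limma without versions. The authors' order of steps, the genome build and the annotation used are not given in the sources used here. The deposited log2 values had nearly equal quartiles on all arrays, with medians from 6.12 to 6.15, and they entered the tests without further normalization. RMA subtracts background, equalizes the distributions of the arrays and summarizes the probes of a row, so a change in the total RNA of a cell cannot be read from these values and small differences near background are compressed. Of 53617 rows, 190 were control rows, 16098 carried 1 gene symbol in the platform annotation, 0 carried several and 37329 were unnamed here. All 16098 were matched through their Entrez identifier to a RefSeq gene table of assembly GRCh38.p14, which was used for current names and for the order of genes only. Where a gene had several rows (779 genes), the row with the highest mean over the 6 arrays stood for it, which left 14884 genes, of which 14871 could be placed on a chromosome and 11916 were protein-coding. Many familiar genes had no named row and were not analysed here.

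The number of arrays limits the precision, with a median standard error of 0.06 on the log2 scale. The 23 background control rows had mean levels from 2.12 to 9.69 with a median of 4.89 (log2), and 1640 genes (11.0%) lay below that median, among them 36 of the called genes. The level of these rows rose broadly with the GC number in their names. On the long-telomere arrays it was 2.08 for GC04, 4.88 for GC14 and 9.67 for GC23. Their median is therefore not a detection limit, and genes above it may also lie near background. Groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as short minus long telomeres, without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. A test on simulated data with the same group sizes recovered 65% of genes changed by 0.5 log2 and 92% of those changed by 1 log2 among 14884 genes, with 4.85% false calls, and 20 simulated data sets without changes gave a mean of 0 calls. The simulation changed 100 genes by each size and drew independent normal noise with each gene's fitted spread. It held no array effects or correlation between genes, so its error rates may not hold for the real arrays.

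The labels ask about genes within 10 Mb of a telomere. The files name no genome build, and distances in Mb were not computed, although start positions in the RefSeq table gave the order of genes. The fallback planned for a case without usable coordinates, written before the data were examined, was applied. A gene was called subtelomeric if it lay within the first 100 protein-coding genes from a chromosome end. The 10 Mb window itself was therefore not tested. This covered 41 ends, leaving out chromosome Y and the 5 short arms of acrocentric chromosomes. The windows of 2, 5 and 20 Mb planned as alternatives became 20, 50 and 200 genes. The length in Mb that these gene counts span was not measured, and the count did not stop at the centromere. Enrichment of called genes and the difference of medians were tested two-sided against all circular rotations of the genes along the genome, a permutation that keeps neighbours together, with Fisher's exact test beside the first. Each end and each of 27 gene lists was tested with camera (preset correlation 0.01, with an estimated correlation beside it) and fry, from limma, with Benjamini-Hochberg adjustment, 26 lists having the 5 measured genes required. The lists were pathways, complexes and markers of muscle and other cell types.

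The groups, lists, tests, alternatives and rule for naming genes were fixed before the data were examined. Named were the 12 highest and 12 lowest called genes whose groups did not overlap, the 6 highest and 6 lowest such subtelomeric genes, all genes of the telomere position effect list, up to 4 genes per other list by smallest p, and TERT. MYOD1, MYF5, DES, MYOG, PAX7, TOP2A, MKI67, NCAM1, TERC, CXCL2, IGFBP3, EYA1, NEB, MYOZ2, TTN, DDIT4, BGN, THBS2, FBN1, VCAN, EDIL3, MMP13, PTGFR, IFI44, CLDN11, RPL22L1, EIF5A2, TNIK, IFIT1, IFIT3, MCM2, MCM3, PCDHB2, PCDHB3 and PCDHB4 were named after their values were seen. XIST and Y-linked genes were tested but are not shown. Alternatives covered renewed quantile normalization, median centring, a level filter, mean of rows, other variance models, array weights, a replicate block, leaving out each array, thresholds, windows, backgrounds and other set tests. In these runs the direction of a list was first taken from camera and, after a first look, from the sign of its median. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.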

Results

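Expression in human myoblasts with long telomeres (15 kb, 3 arrays) was compared with that in myoblasts with short telomeres (6 kb, 3 arrays), all grown to similar population doublings after a telomerase cassette had been excised. The design text asks which genes near a telomere differ between the groups. Array medians ran from 6.12 to 6.15 on the log2 scale. Pairwise correlations across array rows were 0.994 to 0.995 among the long-telomere arrays, 0.993 among the short-telomere arrays and 0.991 to 0.992 between the groups, where rows are not independent replicates. The first principal component held 53.2% of the variance and separated the groups. Besides telomere length, the groups differed in when the cassette was excised and in the sense-strand control rows for Cre recombinase, which were lower with short telomeres by a mean log2 difference of -1.61 (4 rows).

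Chemokines and matrix metalloproteinases were among the genes with the largest increases in cells with short telomeres. LCE3D, a cornified envelope gene of the epidermis, was 13.2-fold higher with short telomeres (log2 difference 3.73 ± 0.09, SE, n = 3 per group, from 7.06 to 10.79). The neutrophil chemokine CXCL8 was 6.63-fold higher (2.73 ± 0.10), the pantetheinase VNN1 6.54-fold (2.71 ± 0.08), the collagenase MMP1 5.03-fold (2.33 ± 0.09) and the complement component C3 4.69-fold (2.23 ± 0.10). CXCL6 (4.64-fold), the interferon-induced chemokines CXCL11 (4.50-fold) and CXCL10 (3.83-fold), the elastase MMP12 (4.38-fold) and the epithelial transcription factor EHF (4.09-fold) also rose, as did PLPPR4 (3.75-fold) and OLFML1 (3.71-fold). Limma's adjusted p (Benjamini-Hochberg) for these genes lay between 1.73e-05 for LCE3D and 0.00276 for OLFML1.

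The largest decreases were smaller and included extracellular matrix genes. ELN, which encodes elastin, was 2.69-fold lower with short telomeres (log2 difference -1.43 ± 0.04, SE, n = 3 per group, from 9.39 to 7.96), and the basement membrane gene NID2 was 2.35-fold lower (-1.23 ± 0.07). SERTAD4 (2.32-fold), TM6SF1 (2.20-fold), the cartilage link protein gene HAPLN1 (2.18-fold), the neurotrophin receptor NGFR (2.11-fold), the proteoglycan gene ACAN (2.09-fold) and the muscle gene MYBPH (2.08-fold) fell as well. NPTX1, ZNF454, LINC01592 and PLXDC2 fell by 2.05-fold, 1.99-fold, 1.98-fold and 1.96-fold.

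Of 14884 genes tested, 1426 (9.58%) passed limma's threshold of 0.05 after Benjamini-Hochberg adjustment. With short telomeres, 851 were higher and 575 were lower (59.7% higher). The median size of the called differences was 0.34 on the log2 scale, and 62 genes differed at least 2-fold, 53 of them higher and 9 lower. At an unadjusted p under 0.05 there were 3686 genes. The values of the groups did not overlap for any of the 1426 called genes, and they did not overlap for 31.5% of all genes, where chance gives 10%. Without 1 array the count was 746 to 907, and it was 2375 with a trended, robust prior. When only genes above the median level were fitted and adjusted again, 1082 were called higher and 1044 lower (50.9% higher). That refit called more genes than the full fit, so its share does not describe the 1426 genes. The excess of higher calls was larger after median centring (901 and 442, 67.1% higher).

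**Figure D1:**
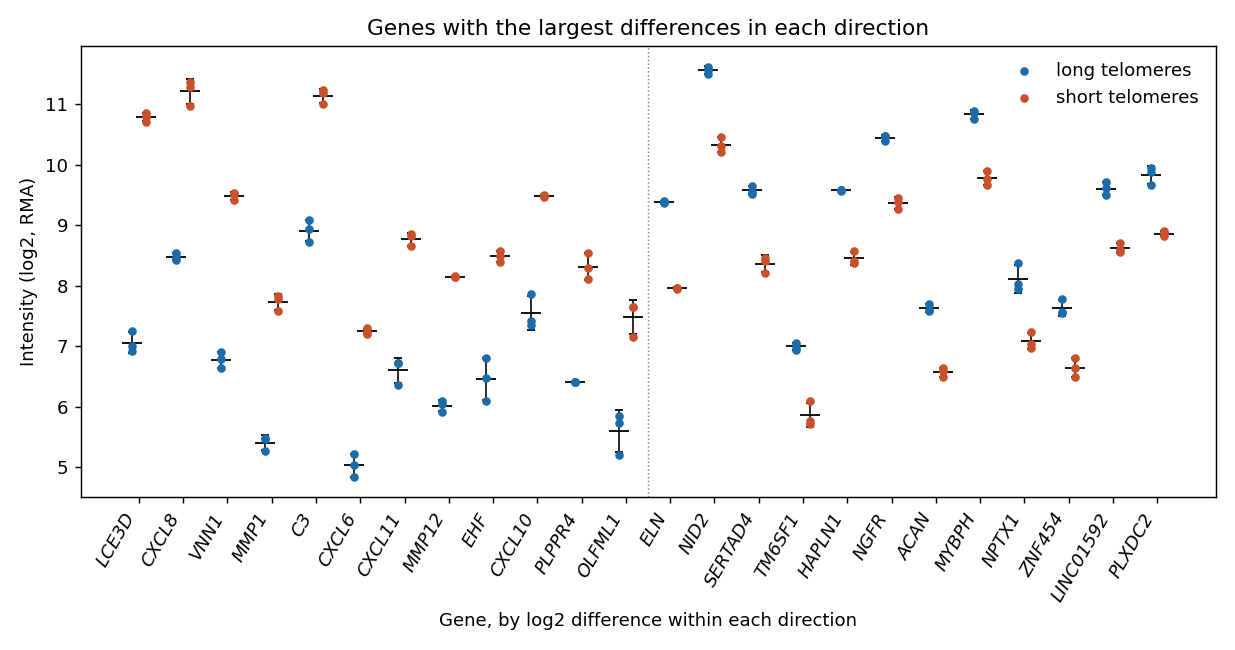
Intensity (log2, RMA) of the 12 genes with the largest increases and the 12 with the largest decreases with short telomeres, with 1 point per array and black marks for mean ± SD of 3 arrays, long in blue and short in orange. LCE3D has the widest gap, from a mean of 7.06 to 10.79, and the groups do not overlap for any gene shown.

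Among genes near chromosome ends, RXFP1, the relaxin receptor gene on the long arm of chromosome 4, had the largest increase with short telomeres (3.46-fold, log2 difference 1.79 ± 0.08, SE, n = 3 per group). The lipid carrier gene APOD (2.42-fold) and the tight junction gene CLDN1 (2.39-fold) on chromosome 3, the antiviral gene RSAD2 on chromosome 2 (2.41-fold), and ANKRD29 (2.01-fold) and the scavenger receptor gene COLEC12 (1.93-fold) on chromosome 18 also rose. TM6SF1 and ACAN on chromosome 15, NPTX1 on chromosome 17, ZNF454 on chromosome 5, PLXDC2 on chromosome 10 and CYTL1 on chromosome 4 (1.82-fold) had the largest decreases. Limma's adjusted p for these 12 genes ran from 0.000124 for RXFP1 to 0.00614 for RSAD2. Their positions ran from gene 6 from the end (COLEC12) to gene 98 (TM6SF1). RXFP1 was gene 97, PLXDC2 gene 96 and ANKRD29 gene 85. Distances in Mb were not measured and the count did not stop at the centromere. These genes therefore need not lie within 10 Mb of a telomere, and those with high numbers may lie far from it.

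Called genes were less frequent near chromosome ends than elsewhere. Of 3123 genes among the first 100 protein-coding genes from an end, 247 (7.91%) passed the threshold, against 1179 of 11748 other placed genes (10.0%). The odds ratio was 0.77 (Fisher's 95% interval 0.664 to 0.890, permutation by rotation p = 0.0105, Fisher's exact p = 0.000287). Fisher's test and interval treat genes as independent, whereas the rotation keeps neighbours together. For genes higher with short telomeres the odds ratio was 0.62 (rotation permutation p = 0.00148), and for genes lower with short telomeres it was 1.04 (p = 0.811). The difference between the directions was not tested. By position, 5.69% of the first 20 genes from an end passed, then 7.58% of genes 21 to 50, 8.84% of genes 51 to 100, 9.24% of the genes from there to 200 and 10.3% of genes beyond 200. The enrichment call was lost without long-telomere array 2 (odds ratio 0.794, permutation p = 0.0624), long-telomere array 3 (0.832, p = 0.0936), short-telomere array 2 (0.837, p = 0.147) or short-telomere array 3 (0.840, p = 0.122).

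The subtelomeric genes as a set sat slightly lower with short telomeres, with a median log2 difference of -0.0198 against -0.00624 elsewhere. That difference of -0.0136 passed the rotation permutation test (p = 0.000403) but not camera (p = 0.225, or 0.274 with an estimated correlation). Fry from limma, which tests the subtelomeric genes against no change and not against other genes, gave a p of 0.0552. The difference was -0.0135 with a window of 20 genes, where the rotation permutation p was 0.0658. No single chromosome end passed camera from limma (0 of 41, smallest adjusted p 0.206, with 7 ends at an unadjusted p under 0.05), while fry, which tests each end on its own, passed 17. Medians were below 0 for 33 of the 41 ends. The median over all genes was itself -0.00921, so 0 is not a neutral reference for that count or for fry.

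**Figure D2:**
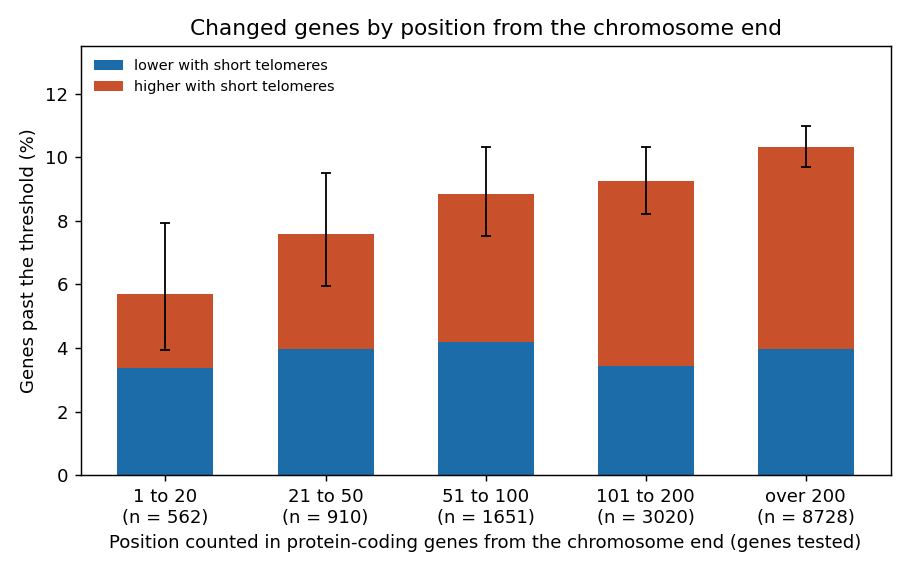
Share of genes past the threshold (%, Benjamini-Hochberg) by position in protein-coding genes from the chromosome end, with lower calls in blue, higher calls in orange and error bars for exact 95% binomial intervals. The intervals treat genes as independent. The share runs from 5.69% for the first 20 genes to 10.3% for genes beyond 200.

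The loci known from telomere position effect work, in which telomere length alters the expression of genes nearby, were measured at 5 of 8 genes. DSP, the desmoplakin gene on the short arm of chromosome 6, fell by 1.36-fold with short telomeres (log2 difference -0.44 ± 0.06, SE, n = 3 per group, limma adjusted p = 0.00598). The ubiquitin-like gene ISG15 had a log2 difference of 0.23 ± 0.11 (adjusted p = 0.247), SORBS2 -0.12 ± 0.06 (adjusted p = 0.263), TERT 0.08 ± 0.05 (adjusted p = 0.339) and FRG1 -0.04 ± 0.07 (adjusted p = 0.771), and none of these passed. Adjusted over the list alone, 1 gene was lower and 0 were higher, which is not independent evidence, since part of this list was drawn from work on these cells. C1S, FRG2 and DUX4 were not analysed here. Of 21 measured genes of distal 4q35, 3 rose (TLR3 by 0.93, IRF2 by 0.30 and ACSL1 by 0.34 on the log2 scale), CENPU fell by 0.21 and 17 did not pass. The counts were the same adjusted over the list alone. The median of that list was -0.04 and its mean 0.03, and camera gave an adjusted p of 0.935.

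Interferon-stimulated genes rose together, with 22 of 29 measured genes higher with short telomeres, 0 lower and 7 not passing (25 higher adjusted over the list alone). Antiviral IFIT2 rose by 1.18 ± 0.11 on the log2 scale (SE, n = 3 per group), IFI44L by 0.84 ± 0.07, USP18 by 0.57 ± 0.05 and IFI35 by 0.54 ± 0.05. The list's median was 0.42 (camera adjusted p = 2.8e-19, and adjusted p = 0.150 with an estimated correlation). Of senescence-associated secretory genes, 11 of 20 rose, 1 fell and 8 did not pass (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.08e-07, and adjusted p = 0.0911 with an estimated correlation). STC1 rose by 1.31 ± 0.05 beside CXCL8, MMP1 and CXCL6, whereas the growth factor binding protein gene IGFBP3 fell by 0.61 ± 0.04, and CXCL2 differed by 0.04 ± 0.11. Of 8 measured complement genes, 3 rose (C3, CFB by 0.86 ± 0.10 and CFI by 0.24 ± 0.05, from 4.41 to 4.65 and below the background rows' median of 4.89; camera adjusted p = 0.0125, and adjusted p = 0.156 with an estimated correlation), also 3 when adjusted over the list alone. Beside these lists, of 7 immune cell markers CD68, a lysosomal gene of macrophages and other cells, rose by 0.44 ± 0.05. The other 6 had a median log2 difference of 0.0223 (SD 0.168), and the marker list did not pass (camera adjusted p = 0.460; 1 higher and 1 lower adjusted over the list alone).

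Part of the cell cycle and proliferation list was lower with short telomeres. Of 34 measured genes, 12 fell, 0 rose and 22 did not pass (14 lower adjusted over the list alone), with CDC6 at -0.39 ± 0.06, MCM5 at -0.30 ± 0.04, MCM6 at -0.28 ± 0.04 and RRM2 at -0.25 ± 0.04 (log2, SE, n = 3 per group). The list passed camera (adjusted p = 8.78e-09, and adjusted p = 0.193 with an estimated correlation). MKI67 differed by -0.12 ± 0.04 (limma adjusted p = 0.137) and TOP2A by 0.000238 ± 0.04 (adjusted p = 0.998). Of 16 measured p53 target genes, 9 rose and 0 fell (11 higher and 1 lower adjusted over the list alone), including SPATA18 by 0.63 ± 0.06, RRM2B by 0.56 ± 0.04, SESN1 by 0.54 ± 0.05 and EDA2R by 0.42 ± 0.05. Camera's adjusted p for them was 3.68e-07, and adjusted p = 0.0911 with an estimated correlation.

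Metabolic lists moved as well. Of 12 cholesterol synthesis genes, 8 fell and 0 rose (11 lower adjusted over the list alone), among them SQLE by 0.32 ± 0.05, DHCR7 by 0.31 ± 0.06, FDPS by 0.27 ± 0.05 and NSDHL by 0.27 ± 0.05 on the log2 scale (camera adjusted p = 3.68e-07, and adjusted p = 0.150 with an estimated correlation). Of 13 unfolded protein and amino acid stress genes, 6 fell and 0 rose (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 7.72e-05, and adjusted p = 0.150 with an estimated correlation). The serine synthesis genes PSAT1 and PHGDH fell by 0.84 ± 0.04 and 0.41 ± 0.05, asparagine synthetase ASNS by 0.52 ± 0.05 and SHMT2 by 0.26 ± 0.04. Of 12 hypoxia and glycolysis genes, 5 rose (7 adjusted over the list alone), namely ADM by 0.30 ± 0.04, MXI1 by 0.29 ± 0.05, NDRG1 by 0.27 ± 0.05, VEGFA by 0.26 ± 0.04 and DDIT4 by 0.26 ± 0.06 (camera adjusted p = 0.00193, and adjusted p = 0.150 with an estimated correlation). Of 12 heat shock and oxidative stress genes, HMOX1 (0.52 ± 0.04) and CAT (0.25 ± 0.04) rose, also 2 adjusted over the list alone (camera adjusted p = 0.00863, and adjusted p = 0.213 with an estimated correlation). Of 10 TGF-beta response genes, SMAD7 fell by 0.26 ± 0.06 (3 lower adjusted over the list alone), and the list's camera adjusted p of 0.0396 became adjusted p = 0.537 with an estimated correlation. The calls of CAT, CFI, DDIT4, DHCR7, FDPS, MXI1, NDRG1, NSDHL, RRM2, SMAD7 and VEGFA were each lost in at least 1 fit without an array, that of SMAD7 also after median centring, that of MXI1 with the mean of all rows and that of CFI with a trended prior. The TGF-beta call was lost with the mean of all rows (adjusted p = 0.0957), with array weights (adjusted p = 0.0563) and without long-telomere array 3 (adjusted p = 0.104) or short-telomere array 1 (adjusted p = 0.0751) or 3 (adjusted p = 0.0909).

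Muscle genes moved in both directions, and neither of their lists passed camera with all genes. Of 16 myogenic regulators, EYA4 (0.46 ± 0.04 on the log2 scale, SE, n = 3 per group) and EYA1 (0.40 ± 0.08) rose, and MEF2C (-0.44 ± 0.06), MSTN (-0.39 ± 0.07) and MYF6 (-0.26 ± 0.05) fell (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.935). MYOD1 differed by 0.11 ± 0.04, MYF5 by 0.03 ± 0.04, MYOG by -0.00467 ± 0.05 and PAX7 by -0.12 ± 0.07, and none passed. Of 18 sarcomere and muscle differentiation genes, KLHL41 (0.50 ± 0.05), MYOZ2 (0.67 ± 0.11), NEB (0.35 ± 0.05) and TTN (0.34 ± 0.08) rose, while MYBPH (-1.06 ± 0.07), XIRP1 (-0.70 ± 0.08) and TNNC1 (-0.68 ± 0.05) fell (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.127). Of 18 collagen and matrix genes, 6 rose, including TNC by 1.29 ± 0.09, DCN by 0.92 ± 0.08 and LOXL4 by 0.77 ± 0.06. ELN, BGN (-0.47 ± 0.04), FBN1 (-0.37 ± 0.05), THBS2 (-0.36 ± 0.04) and VCAN (-0.34 ± 0.05) fell (6 higher and 5 lower adjusted over the list alone; median -0.03, mean 0.03, camera adjusted p = 0.921). Of 12 desmosome genes, PKP2 rose by 0.60 ± 0.06 and DSP, JUP (-0.41 ± 0.06) and PKP4 (-0.27 ± 0.05) fell, with the same counts adjusted over the list alone (camera adjusted p = 0.252). The calls of EYA1, MSTN, MYF6, PKP4, TTN and CENPU were each lost in at least 1 fit without an array, and those of TTN and VCAN with the mean of all rows. Among genes above the median level, the sarcomere list passed camera (median -0.684, adjusted p = 0.0156), against a median of -0.12 with all genes.

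Cell type markers moved in both directions, and no marker list passed camera with all arrays. Of 7 satellite cell and myoblast markers, the adhesion gene VCAM1 rose by 1.04 ± 0.09 on the log2 scale (SE, n = 3 per group), NCAM1 differed by -0.12 ± 0.04 and DES by -0.02 ± 0.04 (1 higher adjusted over the list alone; camera adjusted p = 0.541). Among 6 adipocyte markers, CD36 (0.92 ± 0.05) and PPARG (0.72 ± 0.10) rose (2 higher adjusted over the list alone; camera adjusted p = 0.0853). That list passed camera without long-telomere array 1 (median 0.0568, adjusted p = 0.0470) or short-telomere array 3 (0.0641, adjusted p = 0.0198), against a median of 0.00584 with all arrays. Among 9 fibroblast markers DCN rose and MFAP5 fell by 0.45 ± 0.05 (1 and 1 adjusted over the list alone; camera adjusted p = 0.705). Among 5 pericyte and smooth muscle markers RGS5 rose by 0.39 ± 0.07 (a call lost in 4 of the 6 fits without an array), and NOTCH3 (-0.76 ± 0.09) and CSPG4 (-0.38 ± 0.06) fell (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.128). Of 4 measured Schwann cell markers, too few for a test, NGFR fell (1 lower adjusted over the list alone). None of 8 endothelial markers (camera adjusted p = 0.774), 7 keratinocyte markers (0.779), 17 DUX4 target genes (0.685), 10 respiratory chain genes (0.935) or 14 telomerase and telomere maintenance genes (0.935) passed, over all genes or adjusted over the list alone, and TERC differed by 0.12 ± 0.08. In all, 10 of 26 lists passed camera, 0 with an estimated correlation and 16 by fry, which asks only whether a list's own genes move one way. Median and mean also differed in sign for the myogenic regulators (0.00218 and -0.00369) and the telomere maintenance genes (-0.0117 and 7.6e-05).

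**Figure D3:**
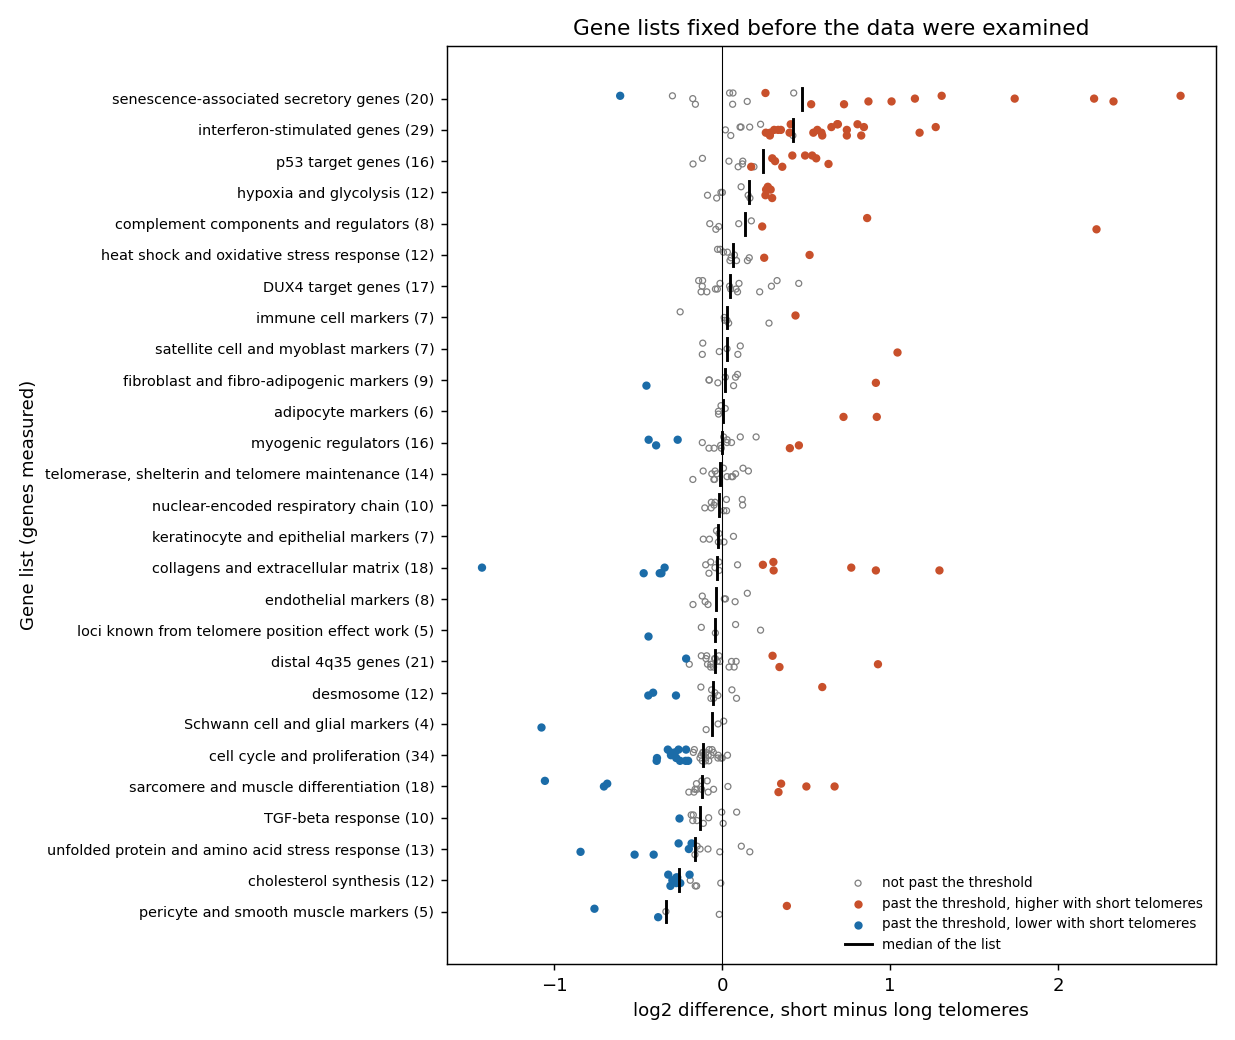
Log2 difference, short minus long telomeres, of each measured gene of 27 lists, ordered by list median (black bar), with genes past the threshold filled (orange higher, blue lower) and others open. The interferon-stimulated list has a median of 0.42 and the cholesterol synthesis list one of -0.26.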

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

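Tests of the control rows were chosen after their values were seen. Rows for Cre recombinase, a bacteriophage enzyme that the array carries as a hybridization control beside bioB, bioC and bioD, differed between the groups, which no comparison of genes had used. The 4 rows of the sense strand, the strand that RNA from cells would fill, were lower with short telomeres by log2 differences of -1.83, -1.40, -1.90 and -1.32. The first 3 passed limma's threshold over all rows (Benjamini-Hochberg adjusted p 0.000927, 0.00242 and 0.0126) and the fourth did not (0.0799), and all 4 rows had each long-telomere array above each short-telomere array. The label records name a cassette flanked by recombination sites and its excision, without naming the enzyme.

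A shift of all bacterial rows of the sense strand is argued against as the whole cause by the 14 bioB, bioC and bioD rows (mean log2 difference -0.0468, SD 0.198; 7 older rows -0.174, or 0.00268 without short-telomere array 2, and 7 newer 0.0802). A larger amount of the mix of hybridization controls on the long-telomere arrays is argued against by the 14 spiked-strand rows of those genes, whose mean was -0.0248 (SD 0.198; older rows -0.210, or 0.150 without that array, and newer 0.161). A larger amount of Cre alone was not seen in the 4 spiked Cre rows (mean -0.0561) but is not excluded, because they lay at 12.3 to 13.6, near the lowest array maximum of 14.2, and the only 1 with room differed by -0.147 (SE 0.178), or 0.0614 without that array. A candidate explanation beside it is a Cre transcript in the cells that is more abundant in the long-telomere cultures. It was prompted by the sense-strand Cre rows, of which 4 of 4 separated the groups in that direction, against 1 of the 14 bacterial rows. That separation is the pattern to be explained and does not test the explanation. Telomere length and the history of the cassette and its excision are not separable in this design, and the Cre transcript hypothesis was found on these arrays and not tested on others.

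Rows without a gene name also changed, at a lower rate than named rows. They were also dimmer, with a median level of 5.67 against 7.31 (log2) for named rows. Whether level accounts for the lower rate was not tested. When all rows except controls were tested together, 668 of 37329 unnamed rows (1.79%) passed the threshold. Of these, 456 were higher and 212 lower with short telomeres. In the same test 559 of 16098 named rows (3.47%) passed, fewer than the 1426 genes called when only named genes were tested. A call with at least a 2-fold difference was found for 71 unnamed rows (0.190%), against 0.367% of named rows.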

How the results depend on the processing

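Leaving out the interferon and secretory list genes was an alternative chosen after seeing the data. The cause of the changes below was not tested, except that fits without 1 array have fewer samples and that a fold minimum or looser threshold changes the count by construction. The count of 1426 genes became 2375 with a trended, robust prior (1385 shared), 2151 at a threshold of 0.10 and 62 with a fold minimum, and 746 to 907 without 1 array. The replicate numbers did not pair the samples (deviation correlations -0.03, -0.04 and -0.10, 0 of 6 arrays closest to their own number), and with the replicate block 602 genes passed (590 shared), with an enrichment odds ratio of 0.797 (rotation permutation p = 0.112). That ratio was 0.763 to 0.840 without 1 array and below 1 in all 20 settings, with its call lost with the block and without long-telomere array 2 or 3 or short-telomere array 2 or 3. The shift was -0.0171 to -0.0123 without 1 array and -0.0135 for 20 genes (permutation p = 0.0658), the only window, fit or background where its rotation call was lost, while camera did not pass it (p = 0.225). Of the ends, 0 passed camera in every setting tried, while fry passed 17. The 10 lists became 9 to 11 without 1 array, 0 with an estimated correlation and 16 with fry. Calls were gained by the sarcomere list in the brighter genes (-0.684, adjusted p = 0.0156) and the adipocyte list without long-telomere array 1 (0.0568, adjusted p = 0.0470) or short-telomere array 3 (0.0641, adjusted p = 0.0198). Higher and lower calls numbered 1082 and 1044 in a refit of only the brighter genes, 901 and 442 after centring and 409 and 193 with the block. Named called genes kept their direction, losing their call in 116 single-array fits and 36 others and keeping it in 556 and 717. Reversed signs occurred in uncalled genes and lists. MYOG was 0.00225 after quantile normalization, 0.0120 after centring and -0.0387 to 0.0318 without 1 array, the telomere maintenance list 0.00497 after centring and -0.0202 to 0.0184, and the respiratory list 0.000594 after centring, 0.00996 in the brighter genes and -0.0360 to 0.00472. Without 1 array, CXCL2 spanned -0.0876 to 0.110, TOP2A -0.0191 to 0.0144, FRG1 -0.108 to 0.0105, and the lists of myogenic regulators -0.00911 to 0.0252, endothelial -0.0840 to 0.0220, immune -0.00907 to 0.0839, DUX4 target -0.0510 to 0.0603, adipocyte -0.00186 to 0.0641, keratinocyte -0.0530 to 0.0425 and position effect genes -0.108 to 0.0105. Signal over background limits the 1640 genes below the background median, and it may limit brighter genes too, since the background rows rose with their GC number.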

Other observations

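Tests of neighbouring genes were chosen after their counts had been seen, except the shuffle within strata, and the counts of other splits were also seen before their tests were written. Families sharing a symbol stem were tested after the lists, and 5 of 449 passed camera (Benjamini-Hochberg), 0 with an estimated correlation (adjusted p = 0.967 for each). The 5 medians kept their sign after quantile normalization and median centring, which is no separate evidence. Centring moves the difference of every gene by the same small amount and could not turn medians of this size. The smallest in size, that of CDCA, went from -0.154 to -0.138. The symbol stem MCM, which takes in replication helicase genes and may take in others, had 7 of 11 genes lower with short telomeres. Among them were MCM2 (-0.32 ± 0.06, log2, SE) and MCM3 (-0.20 ± 0.04). In the clustered protocadherin beta family (PCDHB), whose products are adhesion molecules, 4 of 19 rose, including PCDHB2 (1.80 ± 0.09), PCDHB4 (0.96 ± 0.14) and PCDHB3 (0.52 ± 0.12). The IFIT family had 3 of 5 higher, including IFIT1 (0.74 ± 0.12) and IFIT3 (0.74 ± 0.10), the chemokine family CXCL had 6 of 13 higher and 1 lower, and the CDCA family had 2 of 7 lower. The calls of MCM2, MCM3, PCDHB3 and IFIT1 were lost in at least 1 fit without an array. Genes of the MCM, IFIT and CXCL stems were also on the proliferation, interferon and secretory lists, so these passes partly repeat those of the lists.

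Changed genes lay next to each other in the order of tested genes, where untested genes may lie between neighbours. MMP12 and MMP1 below, for example, were protein-coding genes 259 and 261 from their end. Among 14848 such neighbouring pairs, 123 had both genes called in one direction. The median was 71 and the central 95% range 56 to 87 in 9999 shuffles (permutation p = 1e-04, the smallest they can give). A run on chromosome 3 held CLDN11 (0.38 ± 0.08), RPL22L1 (0.19 ± 0.04), EIF5A2 (0.25 ± 0.05) and TNIK (0.91 ± 0.06), and the calls of the first 3 were lost in fits without an array. Others were PTGFR (0.66 ± 0.08), IFI44L and IFI44 (0.31 ± 0.06, a call lost in 4 of those 6 fits), MMP1, MMP12 and MMP13 (0.87 ± 0.11, from 3.81 to 4.69 and below the background rows' median of 4.89), and VCAN, HAPLN1 and EDIL3 (-0.33 ± 0.04), while the call of VCAN was lost with the mean of all its rows. Cross-hybridization between neighbours of one symbol stem is argued against as the whole cause by the 97 pairs left without such pairs (95% range of the shuffles 48 to 78). Neighbours with similar sequence but unlike names were not tested. Similar level and spread is argued against by a 95% range of 58 to 90 when calls were shuffled within 25 strata. Shared regulation of neighbours may remain, as may overlapping transcripts, which were not tested.

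The lower share of called genes near chromosome ends was weighed with tests written before their values were seen. Differences in level or spread are argued against by a common odds ratio of 0.744 (95% interval 0.643 to 0.860) within 25 strata of level and spread. It was no nearer to 1 than the 0.770 without strata. The interval treats genes as independent, although neighbours changed together, and no rotation was run within strata. Without 8066 genes of symbol stems with 5 or more tested members, the odds ratio was 0.791 (0.648 to 0.961 for independent genes, rotation permutation p = 0.0279). That argues against such genes as the whole cause. The stems include naming groups such as MIR (1088 genes) and LINC (458 genes), so the value does not decide on families of similar sequence. GC content was not tested. That genes near ends respond less often to this contrast is a hypothesis, and its call was lost in 4 of the 6 fits without an array.

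The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1426 genes against 0 in the highest other in size, a shift of -0.0136 against 0.00993, 0 ends against 0, and 10 lists against 7. In the other splits no gene was called, so no odds ratio could be set beside 0.771. The real split was the only 1 of the 10 with as many genes, as large a shift or as many lists, and 0 ends in all 10 compares nothing. Each other split mixed arrays of both groups on each side, which puts any group difference into the spread. Their 0 called genes therefore say nothing about its cause. The other splits still passed 1 to 7 lists. The shift of 0.00993 in another split exceeded the SD of 0.00425 over the rotations, which take no account of the spread between arrays.

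ISG15, an interferon-stimulated gene near a chromosome end, ranked 24 of the 29 measured interferon genes by log2 difference. The median of that list was 0.384 to 0.466 when 1 short-telomere array was left out.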
